A study of Mus musculus with 6 samples.

How the data were processed

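RNA was sequenced from female mouse embryonic stem cells of the line 16.7 TST, labelled wild type, at day 0, day 4 and day 7 of differentiation, with 2 libraries per day. The meaning of TST is not given in the labels. Per the labels' protocols, undifferentiated cells grew with LIF on irradiated mouse embryonic fibroblast feeders. For differentiation they were separated from the feeders, formed embryoid bodies without LIF and were moved to gelatinised plates on day 4. Total RNA was extracted with TRIzol, depleted of ribosomal RNA, and made into libraries with a directional second-strand module. Cas and mus are the allele names of the file headers, which call the cas share Xa and the mus share Xi.

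The authors deposited allele-specific read counts, which are estimated counts in steps of 0.5 per gene, allele and library, and 41.4% of them were not whole numbers. They also deposited the fraction of each allele per gene and library, which equalled the shares recomputed from the counts within 1e-09, with genes without reads listed at 0. The second deposited table gave TPM, whose 372 genes held between 2.17% and 3.12% of the full TPM total per library. Per the submitters' processing notes, Trim Galore 0.4.1, STAR, HOMER 4.10, edgeR and limma were used with the builds GRCm38 and mm10. The role of each tool, whether counting used strand, and how the 372 genes were chosen are not given in the sources used here. All 372 symbols matched the GENCODE M21 annotation of GRCm38 and lay on chromosome X, and coordinates and overlaps are from it.

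A relation within the TPM bears on the expression tests. Per gene, the log2 TPM difference between the day 7 libraries equalled 0.00258 plus 0.0202 times the day 0 difference minus 0.254 times the day 4 difference, with a residual SD of at most 1e-12. The same regression on log2 allele-specific reads gave an R squared of 0.00892. The deposited log TPM therefore lack 1 direction within days, their spread at day 7 is small (SD of the log2 ratio 0.0415, against 0.271 at day 0 and 0.161 at day 4), and adjusted p-values of expression may be too small.

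The mus share is the percent of allele-specific reads from the mus allele. Genes needed a mean of at least 10 such reads per library and a mean TPM of at least 1, and all 372 genes met both. For allele share, counts were rounded to whole numbers and both alleles of all 6 libraries entered edgeR's quasi-likelihood model (version 4.0.16), with library terms, an allele term per day and no scaling between alleles. The common dispersion was 0.00101, on 3 residual degrees of freedom. The fitted prior degrees of freedom were infinite, so a gene was judged by a spread shared across genes and not by its own replicate spread. Changes are log2 changes of the odds of mus to cas reads. Expression was tested with limma's trend method (version 3.58.1) on log2(TPM + 1) over all 6 libraries. P-values were adjusted by Benjamini-Hochberg and called at 0.05. Gene lists were tested with fry, which asks whether a list's genes move on balance one way, and with camera at a preset correlation of 0.01 and at an estimated one. At an estimated correlation camera takes its few degrees of freedom from the libraries. Its p-values are then larger even for lists without correlation between genes. R 4.3.3, scipy 1.17.1 and pandas 2.3.3 were used, and DESeq2 1.42.0 served as an alternative for allele share.

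Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists held 7 measured genes of the X-inactivation centre, 16 escape genes, 25 housekeeping genes, 9 pluripotency or early embryo genes, 18 differentiation genes and 8 fibroblast genes. Col4a5, Col4a6 and Fhl1 were on both of the last lists, and Xist, Jpx and Ftx on both of the first. The 3 autosomal lists (pluripotency, differentiation and fibroblast) had 0 measured members and were not tested. By the rule, named genes were all members of the X-inactivation centre and escape lists, the 10 largest falls and 5 largest rises per measure against day 0 among called genes that moved alike in every pair of libraries, and the members of the other lists with the most reads or highest TPM. Some genes that the rule names are not reported here. Falls in allele share were ranked in percentage points and expression on the log2 scale. Replicate pairs were compared before averaging: allele-specific reads per gene differed by more than counting noise, with chi-square per degree of freedom of 4.07 at day 0, 1.79 at day 4 and 2.80 at day 7. Mus shares lay closer to counting noise, with 1.08, 1.24 and 1.05. Each library counted as 1 sample, as labelled, and the day 7 pair counted as 1 library was an alternative for expression.

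Alternatives were other read minimums, tests, pseudocounts and references, a replicate block, and leaving out each library. Alternatives for unrounded counts, for the missing TPM direction, for the day 7 pair counted as 1 library, and expression fits of only the days compared were added after seeing the data. Where a library is left out, the remaining lone library is assumed to vary like the other days. The methods were tested on simulated data with 200 of 372 genes changed. For allele share at day 4 against day 0, 74% of 100 genes with a log2 change of -1 and 88% of 100 with -2 were called, and 2 of 172 unchanged genes. For expression, 91% of genes with -0.5 and 99% with 1 were called, and 9 of 172 unchanged genes. The allele simulation gave every gene the fitted common dispersion, as the model assumes. The expression simulation drew independent noise, without the exact relation within the TPM. False calls in the real data may therefore be more frequent than in these simulations. Wilson intervals at 95% and limits for a count of 0 (3 counts of the total) cover counting error only, since reads without molecular identifiers are not independent molecules.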

Results

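RNA sequencing followed allele usage and expression along the X chromosome of female mouse embryonic stem cells of the line 16.7 TST at day 0, day 4 and day 7 of differentiation. The genotype label was wild type, the labels do not explain TST in the line's name, and each day had 2 libraries, so 6 libraries in all. Both deposited tables listed the same 372 genes, and all 372 lay on chromosome X of the GRCm38 annotation. The first table counted reads that could be assigned to the cas or the mus allele of each gene, and the second gave total expression as TPM, a transcript abundance scaled to the same total in each library. Column headers of the first table named the cas allele as the active X and the mus allele as the inactive X. Allele-specific reads summed to 113708 and 124488 in the day 0 libraries, 160218 and 160002 at day 4, and 71193.5 and 69742 at day 7. The median gene had 137 reads per library at day 0, 223 at day 4 and 78.8 at day 7, so shares were least precise at day 7. Unless stated otherwise, values are the mean ± SD of the 2 libraries of a day (n = 2). The labels did not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. For allele share that spread was shared across genes, so a gene with discordant replicates could still be called.

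The series is about how Jpx RNA acts on the induction of Xist, and the time course shows how the use of the mus alleles of the X chromosome changed with differentiation. The mus allele supplied 48.6% ± 0.00605 of the summed reads at day 0, 24.8% ± 0.128 at day 4 and 10.3% ± 0.0592 at day 7. The median gene went further, from a mus share of 48.1% ± 0.0723 to 19.8% ± 0.109 and 4.35% ± 0.374. The summed share includes Xist, which was almost wholly mus on every day, and so lies above the summed share of the other genes. The 7 X-inactivation centre genes, Xist among them, had 61.5% ± 0.606 mus of a mean of 2538.5 reads per library at day 7. Within single libraries the Wilson 95% intervals of the summed share were narrow, from 48.3% to 48.9% in day 0 replicate 1 and from 10.1% to 10.6% in day 7 replicate 2, and they cover counting error only. Across the 6 libraries the share fell with day, with Pearson's r = -0.998 (exact two-sided permutation p = 0.0111) and Spearman's rho = -0.956 (exact p = 0.0222). These were the 2 coefficients computed for this relation, and Benjamini-Hochberg adjustment over both leaves 0.0222 for each. Without the 2 libraries farthest from the median day, the day 0 pair, r was -1. With 2 days left and replicates this close, r is near -1 whatever the shape of the relation, so this tests nothing. Leaving out any 1 library kept r between -0.998 and -0.999 (exact p = 0.0333), but rho became -0.949 with an exact p of 0.0667. All these exact p-values, with or without a library left out, are the smallest that the tied days allow. The larger p-values without 1 library were thus fixed by the number of libraries and show no weakening. The 6 libraries fall into 3 days with no library between them, and 2 libraries against 2 cannot reach p = 0.05 in an exact test of 2 days. The labels and tables gave no sequencing batch.

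**Figure D1:**
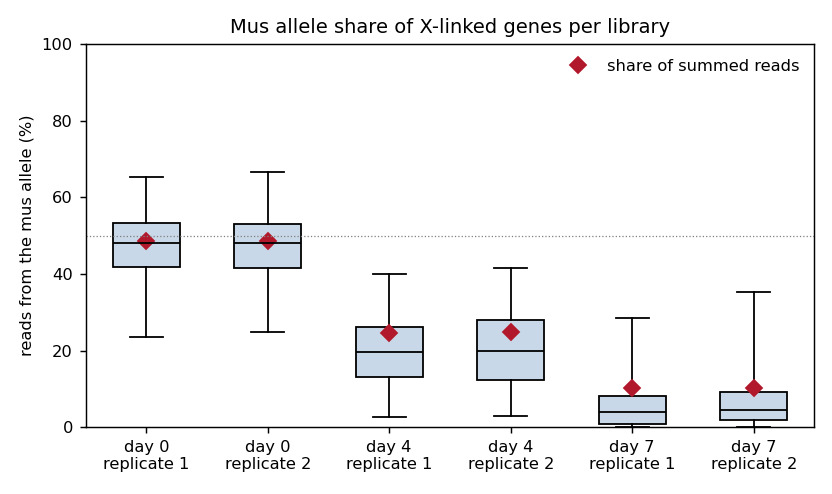
Mus share of allele-specific reads (percent, y axis) over the 372 X-linked genes in each of the 6 libraries (x axis); boxes give the median and the middle range between the quartiles over genes, whiskers reach from the 5th to the 95th percentile, genes beyond them are not drawn, diamonds are the share of summed reads, and the dotted line marks equal alleles. The diamonds sit at 48.6% in both day 0 libraries, at 24.7% and 24.9% at day 4, and at 10.3% in both day 7 libraries.

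At day 0 most X-linked genes were read from both alleles, and 108 of 372 genes departed from an equal share, 72 with fewer and 36 with more mus reads. Xist, the noncoding RNA that coats the X chromosome it is transcribed from, was already almost wholly mus, at 98.9% ± 0.245 of 741.5 reads. Tsix, its antisense repressor, had the opposite bias, with 19.2% ± 4.31 mus reads. Bgn, which encodes the matrix proteoglycan biglycan, stood at 99.9% ± 0.159 mus, and Col4a5, a basement membrane collagen chain, at 98.3% ± 2.38. In the fibroblast list, 5 of 8 members had more mus than cas reads and none had fewer (6 and 0 adjusted over the list alone), with Timp1, an inhibitor of metalloproteinases, at 72.3% ± 0.135 beside Flna at 54.0% ± 0.470 and Msn at 53.1% ± 1.07. In the pluripotency list, 6 of 9 members had fewer mus reads and 1 had more (the same counts adjusted over the list alone), among them Nr0b1, an orphan nuclear receptor of the pluripotency network, at 32.9% ± 0.398. Of 25 housekeeping genes 3 were lower and 4 higher, of 16 escape genes 3 and 7, of 18 differentiation genes 4 and 1, and of 7 X-inactivation centre genes 2 and 1, also when adjusted over the list alone. The count of 108 depended on the test: limma on the empirical logit called 20 genes, 10 with fewer and 10 with more mus reads, and DESeq2 called 37, 22 and 15. The skew toward fewer mus reads thus depended on the test. Relative to each library's median gene 53 were lower and 53 higher, but centring on the median evens the sides by construction, so these counts cannot decide whether the skew is real. Leaving out day 0 replicate 1 or replicate 2 left 62 or 60.

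By day 4 the mus share had fallen at 329 of 372 genes and had risen at 3, Xist, Nr0b1 and Tex11. Limma called 2 rises and DESeq2 0, with 1 at an unadjusted p under 0.05. In the X-inactivation centre, Chic1 went from 51.1% ± 0.0803 to 22.8% ± 0.989 mus, and Rlim, the E3 ubiquitin ligase that promotes Xist expression, from 39.5% ± 1.37 to 20.2% ± 1.47. Jpx, a noncoding RNA gene next to Xist, gave 3 reads in total at day 0, too few for a share, and 69.1% ± 3.0 mus reads at day 4 among 120 reads. Ftx, another noncoding RNA gene, had 45.1% ± 0.0862 and 39.7% ± 1.23, a difference that did not pass the test. In this list 4 of 7 members fell and 1 rose, but 3 and 0 when adjusted over the list alone, and relative to each library's median gene 1 was lower and 3 higher.

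Genes known to be expressed from the inactive X in mouse, the escape list, also lost mus reads by day 4 at 13 of 16 members, with Xist higher and Ftx and Jpx not passing (13 and 1 adjusted over the list alone), while relative to each library's median gene 10 members were higher and 1, Shroom4, was lower. The histone demethylase gene Kdm6a kept 42.5% ± 1.23 mus reads, Utp14a, which acts in ribosome assembly, 41.0% ± 0.913, the RNA helicase gene Ddx3x 36.5% ± 2.32, and the histone demethylase gene Kdm5c 36.2% ± 1.46. Mid1, a ubiquitin ligase gene, was at the other end with 1.91% ± 0.465. The median member of the list had a mus share of 36.6% ± 1.44, against 31.1% ± 3.63 for pluripotency genes, 24.4% ± 0.636 for housekeeping genes, 14.2% ± 1.94 for differentiation genes and 18.7% ± 0.223 for fibroblast genes. Of the housekeeping genes 24 of 25 fell, all except Rpl10, as did 18 of 18 differentiation genes and 8 of 8 fibroblast genes, with identical counts adjusted over the list alone, although relative to the median gene 11 housekeeping genes were higher and 3 lower, 3 differentiation genes higher and 6 lower, and no fibroblast gene higher and 6 lower. The pluripotency list was divided, with 4 of 9 members lower (Dusp9, Morc4, Tfe3 and Zfp185), 2 higher (Nr0b1 and Tex11) and Rhox6, Rhox9 and Xlr3a not passing, also when adjusted over the list alone. Relative to the median gene, 7 members were higher and 0 lower. The fall of each of the 6 lists passed fry, the largest adjusted p being 0.00889 for the X-inactivation centre. Since 329 of 372 genes fell, almost any list of these genes was likely to pass fry, so passing marks no list out. By summed reads the X-inactivation centre went the other way, from 46.1% ± 0.319 mus at day 0 to 57.1% ± 2.31 at day 4. Its median member nevertheless fell from 44.0% ± 1.60 to 22.8% ± 0.989. Xist, almost wholly mus on both days, rose in expression, and the list's reads went from 3513.2 to 9845 per library. The summed share thus weighs Xist more at day 4 and does not show a general gain of mus reads among members. The escape list, which shares Xist with the X-inactivation centre, had summed shares of 54.7% ± 0.843 and 55.3% ± 0.996. Camera, which compares a list with the other genes, passed 3 lists at the preset correlation. The X-inactivation centre and pluripotency lists lay higher than the other genes (adjusted p = 0.00066 for each) and the fibroblast list lower (0.0176). The larger fall of the fibroblast list goes with its higher start. Its median member had 63.2% ± 0.208 mus reads at day 0, against 48.1% ± 0.0723 for the median gene of the library. At day 4 its 18.7% was near the median gene's 19.8% ± 0.109. With an estimated correlation none passed, and the X-inactivation centre had adjusted p = 0.254, the pluripotency list 0.254, the escape list 0.502, the fibroblast list 0.506, the housekeeping list 0.623 and the differentiation list 0.640. The estimated correlation of the pluripotency list was negative (-0.098), yet its unadjusted camera p went from 4.48e-05 to 0.0233. Camera has few degrees of freedom in this form, so failing it does not show that correlation within a list made its difference.

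The largest falls in mus share at day 4 were ranked in percentage points, which by construction favours genes with high mus shares at day 0. Mid2 went from 94.1% ± 8.32 of 12.5 reads to 0 of 173.5 reads, which allows a share of up to 1.73%. Col4a5 reached 7.70% ± 7.82 and its neighbour Col4a6 went from 79.8% ± 6.80 to 0.332% ± 0.470. Cnksr2, Slc38a5, Zc3h12b, Aff2, Dock11 and Dgkk were also among the 10 largest, each with day 4 means below 10% and with 6.5 to 85.5 reads behind the day 0 share, of which the Aff2 call was lost in limma, with the replicate block and without day 0 replicate 1 or day 4 replicate 1. The rise of Nr0b1 to 39.8% ± 1.89 had a log2 odds change of 0.43 ± 0.13 (SE) and adjusted p = 0.000714 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in both day 4 libraries, and it was lost in limma and in DESeq2. Xist reached 99.6% ± 0.103 (adjusted p = 0.0393 in the same edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a call lost in DESeq2, with the replicate block (0.05999) and without day 0 replicate 1 (0.0877), day 0 replicate 2 (0.353) or day 4 replicate 1 (0.103). The Tex11 call, from 22.2% ± 0.477 to 47.2% ± 20.8, was lost in limma, in DESeq2, with the replicate block and without either day 0 library or day 4 replicate 2. The fall of Tsix to 11.7% ± 5.99 was lost in limma, in DESeq2 and without day 0 replicate 2 or day 4 replicate 2, and that of Kdm6a in limma, in DESeq2 and without day 0 replicate 1. Over all genes the median log2 odds change was -1.82, and relative to each library's median gene 70 genes were lower and 82 higher.

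At day 7 the mus share was lower than at day 0 at 333 of 372 genes and higher at 2, Xist and Trap1a. Limma called 6 rises and DESeq2 2. Xist was 99.8% ± 0.120 mus among 2994 reads, with adjusted p = 0.00487 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, lost without day 0 replicate 2 (0.122). Rlim had fallen to 4.97% ± 0.517, Chic1 to 2.56% ± 3.63 and Ftx to 17.1% ± 2.98. Jpx stood at 54.2% ± 5.89 of 23 reads and Tsix at 26.4% ± 17.1 of 13.5 reads, and neither differed from day 0 in the test. In the X-inactivation centre list 4 of 7 members were lower and 1 higher, also when adjusted over the list alone, and relative to the median gene 0 were lower and 3 higher.

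The escape list was spread widely at day 7, with 14 of 16 members lower than at day 0, Xist higher and Jpx not passing (14 and 1 adjusted over the list alone), and relative to the median gene 11 higher and Shroom4 lower. Kdm6a had 37.4% ± 10.7 mus reads, a fall lost in limma, in DESeq2 and without day 0 replicate 1 or day 7 replicate 1. Of the others, 1810030O07Rik had 30.6% ± 6.88, Ddx3x 29.5% ± 0.150, Utp14a 29.1% ± 0.724, Kdm5c 24.8% ± 2.21 and 5530601H04Rik 21.8% ± 1.74. The noncoding RNA gene Firre had 15.2% ± 1.38, Pbdc1 14.5% ± 0.297 and the translation initiation factor gene Eif2s3x 8.92% ± 0.823. Syap1 at 5.36% ± 0.902, Shroom4 at 5.27% ± 0.116, Mid1 at 1.41% ± 0.857 and 4933407K13Rik at 1.22% ± 1.72 lay near or below the share of the median gene. Housekeeping genes were lower at 23 of 25 members, with Hnrnph2 and Rpl10 not passing, and had a median of 8.33% ± 0.242, while relative to the median gene 10 were higher and 2 lower. Huwe1 fell to 8.53% ± 0.530 and Usp9x to 10.1% ± 0.238, whereas the ribosomal protein gene Rps4x kept 39.0% ± 0.0951, a fall lost in DESeq2 and without day 0 replicate 1. All 18 differentiation genes and all 8 fibroblast genes were lower, with medians of 3.16% ± 0.618 and 4.48% ± 0.925. Relative to the median gene, 3 differentiation genes were lower and 2 higher, and 4 fibroblast genes lower and 1 higher. In the pluripotency list, with a median of 5.25% ± 0.693, 4 of 9 were lower and 5 did not pass, among them Nr0b1 at 40.2% ± 6.38 of 80 reads. Relative to the median gene 1 was lower and 3 higher. Counts of these 4 lists were identical adjusted over the list alone.

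Col4a5 had the largest fall by day 7, from 98.3% to 0.739% ± 0.0386, followed by Bgn, which reached 5.57% ± 2.11. Mid2 gave no mus read among 33.5, which allows up to 8.96%. Col4a6, Cnksr2, Slc38a5, Timp1, Fundc2, Gemin8 and Iqsec2 completed the 10, each below 5% mus, though Fundc2 had only 9 reads, where a count of 0 allows up to 33.3%. Trap1a, a tumour rejection antigen gene, went from 56.1% ± 1.10 to 86.8% ± 18.6 of 18.5 reads, a call lost without day 7 replicate 1 (adjusted p = 0.424, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The median log2 odds change was -4.14, and relative to the median gene 40 genes were lower and 63 higher. All 6 lists passed fry with adjusted p of at most 0.00175, which the fall at most genes again made likely for any list. At the preset correlation, camera placed the X-inactivation centre (adjusted p = 0.00066) and pluripotency (0.0176) lists higher than the other genes. None passed camera with an estimated correlation, where adjusted p = 0.254 for the X-inactivation centre, 0.273 for pluripotency, 0.623 for the escape and fibroblast lists, 0.640 for housekeeping and 0.887 for differentiation.

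**Figure D2:**
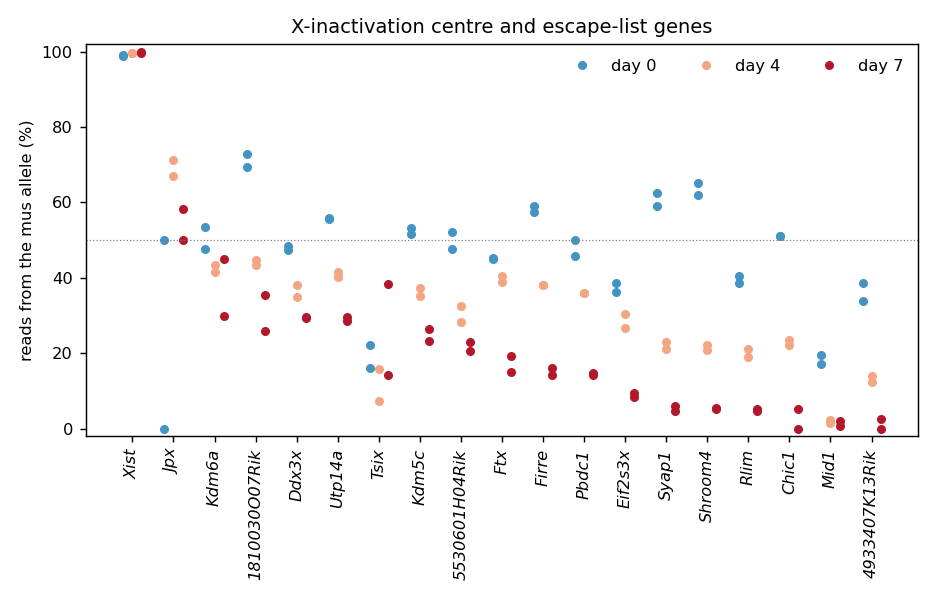
Mus share of allele-specific reads (percent, y axis) of X-inactivation centre and escape genes (x axis), 1 point per library, coloured by day, with the dotted line at equal alleles. Xist stays above 98% in all 6 libraries, Kdm6a, Ddx3x and Utp14a keep day 7 means of 37.4%, 29.5% and 29.1%, and Mid1 falls to 1.41%.

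Between day 4 and day 7 the mus share fell further at 249 of 372 genes and rose at 3, Amot, Eras and Rtl8c. Limma on the empirical logit called 260 falls and 16 rises, and DESeq2 228 and 3. In the escape list 11 of 16 members fell and none rose (11 and 0 adjusted over the list alone), with Kdm5c going from 36.2% to 24.8%, Firre from 38.0% ± 0.0102 to 15.2% and Eif2s3x from 28.6% ± 2.70 to 8.92%. Kdm6a, 5530601H04Rik, Mid1, Jpx and Xist did not pass. Of the X-inactivation centre genes Chic1, Ftx and Rlim fell, 3 of 7 in both adjustments. Housekeeping genes fell at 18 of 25, pluripotency genes at 4 of 9 and differentiation genes at 9 of 18 (18, 4 and 8 adjusted over the list alone). The fibroblast list had 6 of 8 lower and 1 higher, also adjusted over the list alone, the exception being Amot, a regulator of Hippo signalling, which went from 2.72% ± 0.411 to 5.18% ± 0.273. The other 2 rises were chosen for mention after their values were seen: Eras, a Ras gene of embryonic stem cells, had 8.68% ± 2.85 at day 4 and 32.2% ± 29.9 of 16.5 reads at day 7, and Rtl8c 0.409% ± 0.00771 and 3.88% ± 2.83. Relative to the median gene 20 genes were lower and 47 higher. In the lists these were 0 and 7 escape genes, 0 and 3 X-inactivation centre genes, 1 and 5 housekeeping genes, 1 and 1 pluripotency genes, 2 and 3 differentiation genes and 2 and 2 fibroblast genes. All 6 lists passed fry with adjusted p of at most 0.00863, which was likely for any list since 249 of 372 genes fell. In camera the smallest adjusted p was 0.0764 at the preset correlation and 0.502 with an estimated one.

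Total expression of the X-inactivation centre changed strongly by day 4. Xist rose from 11.3 ± 0.573 to 103 ± 7.45 TPM, 9.18-fold, Ftx from 7.54 ± 0.159 to 71.0 ± 3.76 TPM and Jpx from 0.248 ± 0.0442 to 4.27 ± 0.663 TPM. Tsix fell from 69.8 ± 3.79 to 22.3 ± 3.77 TPM and Chic1 from 26.5 ± 2.28 to 15.6 ± 0.164 TPM, while Rlim, at 201 ± 24.9 and 220 ± 0.616 TPM, did not pass the test. The rise of Xist was 3.09 ± 0.07 (SE) on the log2(TPM + 1) scale, with adjusted p = 5.85e-08 in limma with Benjamini-Hochberg adjustment, and that of Jpx 2.07 ± 0.12, with adjusted p = 3.76e-06, both higher in 2 of 2 day 4 libraries. On this scale the change of low genes such as Jpx is understated. Xist (chromosome X, 103460366 to 103483254, minus strand) overlaps Tsix (103431517 to 103484957, plus strand), and Jpx (103493556 to 103565696, plus strand) overlaps Ftx (103560907 to 103623790, minus strand). The sources used here do not state whether counting used strand, so reads in the overlaps may not be separated.

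**Figure D3:**
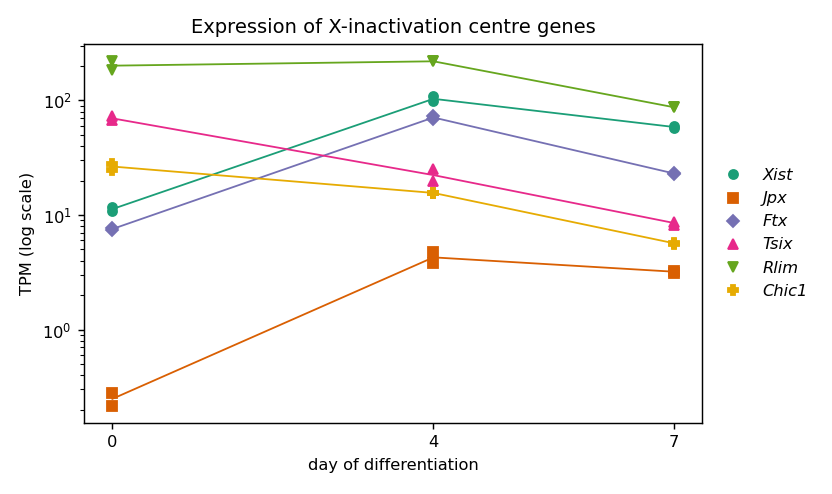
Expression (TPM, log scale, y axis) of 6 X-inactivation centre genes against day of differentiation (x axis), with 1 point per library and lines through the day means. Xist rises from 11.3 to 103 TPM by day 4 and stands at 58.6 TPM at day 7, and Tsix falls from 69.8 to 8.51 TPM.

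Over all 372 genes, 151 were lower and 154 higher in expression at day 4 than at day 0, and 185 and 128 after centring each library on its median gene. The pluripotency list fell at 8 of 9 members, all except Zfp185, under both scalings and adjusted over the list alone: Nr0b1 from 324 ± 5.0 to 67.6 ± 2.77 TPM, Rhox9, a homeobox gene, from 279 ± 4.59 to 69.8 ± 5.78, Rhox6 from 203 ± 21.4 to 49.8 ± 5.90, and Dusp9, a phosphatase of ERK signalling, from 545 ± 11.8 to 145 ± 7.25. Escape genes fell at 5 and rose at 8 of 16 members (7 and 6 after centring), housekeeping genes at 10 and 6 of 25 (17 and 5), differentiation genes at 7 and 8 of 18 (10 and 7) and fibroblast genes at 3 and 3 of 8 (5 and 3). Adjusted over the list alone, 9 housekeeping genes fell, and the other counts were the same. Among differentiation genes Col4a6 rose from 0.453 ± 0.186 to 8.24 ± 0.809 TPM and Bex1 fell from 906 ± 56.0 to 465 ± 24.9 TPM. Among fibroblast genes Bgn fell from 90.8 ± 10.02 to 1.89 ± 0.460 TPM and Timp1 from 185 ± 3.62 to 44.7 ± 3.69 TPM, while Amot rose from 11.4 ± 1.21 to 168 ± 21.4 TPM.

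Bgn had the largest fall in expression at day 4, ahead of Pcsk1n, Ripply1, AU015836, Nr0b1, 8030474K03Rik, Pnma5, Rhox1, Timp1 and Rhox6. Day 0 cells grew on fibroblast feeders and were separated from them for differentiation, so the falls of the fibroblast-list genes Bgn and Timp1 are not separable from a loss of feeder RNA. Among the largest rises were those of Fndc3c1, from 1.08 ± 0.129 to 65.3 ± 2.64 TPM, Rtl8c, from 2.25 ± 0.207 to 70.9 ± 1.39, Irs4, an adaptor of insulin receptor signalling, from 1.40 ± 0.144 to 48.9 ± 9.37, and Apln, which encodes the peptide apelin, from 7.01 ± 0.0934 to 120 ± 17.8. In fry, the X-inactivation centre (adjusted p = 1.2e-05), escape (0.000441) and differentiation (0.00728) lists moved up on balance and the pluripotency list down (1.5e-05). The fibroblast list (0.0479) passed narrowly, and housekeeping genes (0.285) did not pass. The median change of the differentiation list, -0.04, differed in sign from its mean of 0.19 and its test. That of the escape list, 0.12, lay well below its mean of 0.59. Its 8 higher members include Xist, Jpx and Ftx, which are also on the X-inactivation centre list, and 5 members were lower. The test therefore does not show a rise of escape genes in general. With an estimated correlation in camera, adjusted p = 0.691, 0.866, 0.960, 0.337 and 0.906 for the X-inactivation centre, escape, differentiation, pluripotency and fibroblast lists. The fibroblast call ended when the missing direction of the TPM was added as a term (adjusted p = 0.243) and with the replicate block (0.604).

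At day 7 expression was lower than at day 0 at 201 genes and higher at 115, and 173 and 164 after centring, with a median log2 change of -0.37. Xist stood at 58.6 ± 1.06 TPM, 5.20-fold above day 0, Jpx at 3.20 ± 0.111 and Ftx at 23.0 ± 0.329 TPM, all 3 higher than at day 0. Tsix at 8.51 ± 0.368, Chic1 at 5.66 ± 0.0321 and Rlim at 87.1 ± 0.267 TPM were lower. Pluripotency genes were lower at 7 of 9 members, with Morc4 and Zfp185 higher: Nr0b1 reached 13.8 ± 0.157, Rhox9 12.6 ± 0.286 and Rhox6 9.96 ± 0.266 TPM. Escape genes were lower at 10 and higher at 5 of 16, and housekeeping genes at 15 and 4 of 25, with Atrx, a chromatin remodeller gene, going from 278 ± 42.2 to 36.6 ± 0.302 TPM and Rps4x from 570 ± 15.8 to 201 ± 1.77 TPM. After centring these were 9 and 5, and 13 and 10. Differentiation genes were split 8 and 8 of 18 (8 and 9 after centring), with Gpc3, a heparan sulphate proteoglycan gene, up from 210 ± 4.67 to 337 ± 0.228 TPM and Bex1 down to 301 ± 4.86. Fibroblast genes were 2 lower and 4 higher of 8 (2 and 6 after centring). Every list had these counts also when adjusted over the list alone.

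The largest falls at day 7 included 4930519F16Rik, Rhox1, Nr0b1, Rhox9, Eras, Rhox6, Trap1a, Nexmif, 8030474K03Rik and Pnma5. Eras went from 155 ± 19 to 6.59 ± 0.0258 TPM, Trap1a from 469 ± 67.3 to 27.7 ± 0.326 and Nexmif from 68.0 ± 2.25 to 3.32 ± 0.0458. The largest rises were Plac1, a trophoblast gene, from 0.324 ± 0.289 to 83.3 ± 5.71 TPM, Col4a6 to 78.2 ± 1.19, Asb12 from 0.265 ± 0.0954 to 56.0 ± 0.579, Spin2c from 5.55 ± 1.01 to 212 ± 5.90 and Capn6, a calpain family gene, from 5.42 ± 0.932 to 177 ± 5.25. Plac1 rose by 6.01 ± 0.16 (SE) on the log2 scale, with adjusted p = 2.7e-08 in limma with Benjamini-Hochberg adjustment, in both day 7 libraries. In fry, the X-inactivation centre, differentiation and fibroblast lists moved up on balance and the other 3 down, each with adjusted p of at most 0.0120. With an estimated correlation in camera, adjusted p = 0.710, 0.858, 0.640, 0.960, 0.866 and 0.691 for the X-inactivation centre, differentiation, fibroblast, escape, housekeeping and pluripotency lists. The escape call ended with the missing TPM direction as a term (adjusted p = 0.121) and with the replicate block (0.072).

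From day 4 to day 7 all 7 X-inactivation centre genes fell in expression and all 8 fibroblast genes rose, also when adjusted over the list alone, and after centring 6 and 8 did. Xist fell by 0.81 on the log2 scale, Ftx by 1.58 and Jpx by 0.32. Bgn rose from 1.89 to 27.7 ± 1.70 TPM and Col4a5 from 4.42 ± 0.292 to 60.5 ± 0.895. Over all genes 225 were lower and 95 higher, and 157 and 163 after centring. Escape genes were 13 lower and 1 higher of 16 (8 and 3 after centring), housekeeping 15 and 6 of 25 (11 and 13), pluripotency 5 and 3 of 9 (5 and 4) and differentiation 10 and 7 of 18 (5 and 10), with the same counts adjusted over the list alone. In fry the X-inactivation centre, escape, housekeeping and pluripotency lists moved down and the fibroblast list up, each with adjusted p of at most 0.000428, and the differentiation list did not pass (0.131). With an estimated correlation in camera, adjusted p = 0.337 for the fibroblast list, 0.640 for the X-inactivation centre, 0.833 for escape and 0.960 for both other lists.

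No relation between the distance of a gene from Xist and the fall of its mus share passed the test. Across the 372 genes, which are not independent replicates, Spearman's rho of distance and log2 odds change was -0.0236 for day 4 against day 0 (permutation p = 0.650), 0.0294 for day 7 against day 0 (permutation p = 0.571) and 0.0351 for day 7 against day 4 (permutation p = 0.499), and adjusted over the 3 relations all gave 0.650. Pearson's r was -0.0127, 0.0259 and 0.0407 (permutation p = 0.806, 0.617 and 0.433). The median gene within 10 Mb of Xist had a mus share of 19.5% ± 0.174 at day 4 (73 genes), against 26.1% ± 4.56 between 10 and 25 Mb (5 genes), 18.8% ± 0.154 between 25 and 50 Mb (154 genes) and 20.9% ± 0.283 beyond 50 Mb (140 genes).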

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

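The number of genes with a changed mus share moved by less than 1.5 times under every alternative except the one relative to each library's median gene, and it lay between 298 and 335 for day 4 against day 0, 313 and 342 for day 7 against day 0, and 222 and 276 for day 7 against day 4. The expression counts lay between 271 and 321, 298 and 337, and 301 and 334. The read and TPM minimums removed no gene, so dropping them tested nothing. The correlation of day with mus share lay between -0.992 and -0.9996 under the other ways of combining genes, and between -0.998 and -0.999 without 1 library (exact p = 0.0333). Relative to the median gene, 152, 103 and 67 genes changed in the 3 comparisons, since this alternative by construction removes the change common to the X chromosome, and 116 genes had unequal alleles at day 7. At day 0, limma gave 20 unequal genes, DESeq2 37, and leaving out 1 library between 60 and 111, the low end with fewer day 0 samples; the cause of the difference between tests was not tested. Of 18 list tests, camera with a preset correlation passed 5 for allele share and 2 for expression, and with an estimated correlation 0 and 0. The 2 for expression were pluripotency, lower for day 4 against day 0 (adjusted p = 0.00576), and fibroblast, higher for day 7 against day 4 (0.000415). Camera asks another question than fry. With an estimated correlation it also has few degrees of freedom, so passing 0 tests does not mark the lists as like the other genes. Among single named genes, DESeq2 lost 10 calls of allele share and limma 7, and leaving out 1 library lost between 1 and 12, while for expression it lost between 1 and 7; the missing TPM direction as a term lost 3 and the day 7 pair counted as 1 library 4. DESeq2 on expression was not run, because the values are TPM. With 69742 to 160218 reads per library, depth limits mostly genes such as Jpx and Tsix, whose day 7 shares rest on 23 and 13.5 reads.

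For allele share the replicate numbers showed no pairing of the libraries: deviations of same-numbered libraries correlated at -0.096, 0.061 and -0.128. For expression these correlations were -0.013, 0.127 and -0.895. The last, of day 4 and day 7, goes with the exact relation within the TPM, where the day 4 difference has a coefficient of -0.254. It therefore does not tell whether the libraries were paired. With the replicate block, 325, 329 and 245 genes changed in allele share and 305, 319 and 319 in expression, and 81, 350 and 333 genes had unequal alleles at day 0, 4 and 7. With the block 18 list tests of allele share and 14 of expression passed, those of the fibroblast list at day 4 and the escape list at day 7 being lost for expression. Among single named genes it lost 5 calls of allele share and 2 of expression.

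Relative to the median gene, these log2 odds changes had the opposite sign to the change itself. For day 4 against day 0 they were 1810030O07Rik 0.24, 4930519F16Rik 1.76, 4933407K13Rik 0.0133, 5530601H04Rik 0.69, AU015836 1.56, Atrx 0.42, Bex1 0.33, Chic1 0.056, Ddx3x 1.19, Dusp9 0.59, Eif2s3x 1.31, Firre 0.69, Ftx 1.55, Gpc3 0.32, Hcfc1 0.17, Huwe1 0.59, Kdm5c 0.92, Kdm6a 1.40, Map7d3 0.0678, Nexmif 1.79, Pbdc1 1.17, Pnma5 1.80, Rhox6 1.83, Ripply1 1.79, Rlim 0.50, Rps4x 1.32, Tfe3 0.37, Timp1 0.15, Tsix 1.01, Uba1 1.19, Usp9x 0.91, Utp14a 1.02. For day 7 against day 0 they were 1810030O07Rik 1.47, 5530601H04Rik 2.03, Atrx 0.23, Bex1 1.35, Capn6 0.52, Ddx3x 2.77, Eif2s3x 1.37, Eras 3.13, Firre 0.95, Flna 1.27, Ftx 1.95, Gpc3 0.88, Hcfc1 0.85, Huwe1 0.45, Kdm5c 2.17, Kdm6a 3.04, Map7d3 1.16, Nexmif 3.10, Pbdc1 1.57, Pcsk1n 0.43, Pnma5 3.01, Rhox6 3.30, Rhox9 3.71, Rlim 0.26, Rps4x 3.46, Spin2c 0.0927, Tfe3 0.16, Uba1 1.85, Usp9x 0.77, Utp14a 2.29. After centring expression on the median gene, 5530601H04Rik had -9.685e-05 at day 4 and 4933407K13Rik 0.0397 at day 7. These signs follow from subtracting the median change.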

Other observations

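The 9 genes other than Xist with a mus share over 70% at day 0 and at least 10 reads were 1810030O07Rik, Bgn, Cnksr2, Col4a5, Col4a6, Mid2, Rhox1, Slc38a5 and Timp1. Rhox1, a reproductive homeobox gene, kept 67.4% ± 12.8 mus reads at day 4 on 20.5 reads while its expression fell from 44.9 ± 0.283 to 9.95 ± 1.03 TPM. Pnma5, whose expression also fell by day 4, had 49.5% ± 1.65 mus reads at day 4 and 37.2% ± 11.6 at day 7, its day 7 fall in share being lost in limma, in DESeq2 and without day 7 replicate 1. AU015836 had 28.0% ± 0.0985 at day 4 and 0 of 100.5 reads at day 7, which allows up to 2.99%.

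Multiplying TPM by each allele's share splits expression by allele. The summed cas TPM was 15656 ± 758 at day 0, 20881 ± 124 at day 4 and 19864 ± 153 at day 7, and the mus TPM 14806 ± 337, 6414 ± 182 and 1857 ± 54.9. The median gene's cas TPM was 1.5-fold its day 0 value at day 4 and 1.38-fold at day 7, and its mus TPM 0.476-fold and 0.140-fold.

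All tests below were chosen only after the result was seen. Genes whose TPM fell by day 4 kept more mus reads. The 93 genes with the lowest TPM ratio had a median day 4 mus share of 25% and the 93 with the highest 11.2%. Distance from Xist is argued against, since its Spearman's rho was 0.01702 with the day 4 mus share and -0.079 with the TPM change, and so is counting noise, with -0.5388 among 265 genes with at least 100 reads in each day 4 library. Across 370 genes, which are not independent replicates, Spearman's rho of TPM change and day 4 mus share, taken from different replicates, was -0.501 (permutation p = 1e-05, the smallest 100000 resamples can give). At day 7 it was -0.164 across 365 genes and -0.315 among 281 genes with at least 20 reads in each day 7 library. A share of cells that kept both X chromosomes active and still expressed genes of undifferentiated cells, and a difference between genes in the time of silencing within every cell, both stay open and untested, because both allow this relation and bulk RNA does not separate cells.

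The excess of mus reads at day 0 may come in part from RNA of feeder fibroblasts, on which the day 0 cells grew. The labels describe separation from the feeders for differentiation and do not say whether the day 0 cells were separated before harvest. The fibroblast list's median day 0 mus share, 63.2%, lay at percentile 99.98 of 10000 lists of the same size matched on TPM, whose median was 47.6%. Loss of cas reads in mapping on every day would leave the odds change relative to the median gene near that of other genes. For the 8 genes over 70% at day 0 with at least 10 reads at day 7, this log2 change had a median of -4.554. Of these, 5 were lower (Bgn, Cnksr2, Col4a5, Col4a6 and Mid2), 1810030O07Rik was higher at 1.47, and Slc38a5 and Timp1 did not pass. At day 7 the 5 had mean mus shares of 5.57%, 0.943%, 0.739%, 0.561% and 0, on 33.5 to 1564 reads. Nearly all their reads were then cas, which argues against a near-complete loss of cas reads for these 5. A partial loss stays open for them, because strong silencing of single genes would lower the change too. For the rest of the 8 any loss stays open. Flna and Msn, at 54.0% and 53.1%, were near equal, 3 of the 8 list genes are also on the differentiation list, and the labels do not give the strain of the feeders. A higher expression of these genes from the mus allele in stem cells stays open and was not tested.

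The exact relation between the day 7 TPM pair and the other pairs is what an adjustment of log TPM for a factor within days would leave: R squared was 1 in the TPM and 0.008924 in the allele-specific reads. A single day 7 library sequenced in 2 runs is argued against as the cause of this relation, because noise of its runs would not follow the differences of other days, whereas R squared was 1. Whether the day 7 pair came from 1 library stays open: chi-square per degree of freedom between the pair was 2.797 for allele-specific reads, which are estimated counts, and 1.051 for mus shares (p = 0.313), and the median fold in TPM was 1.013. Such an adjustment is not recorded in the sources used here and may explain the small day 7 spread. No biological explanation was tested for this pattern.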
